A study of Homo sapiens with 48 samples.

How the data were processed

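RNA of H1975 cells was sequenced as unstranded paired-end libraries, 3 per group in 16 groups. Per the labels, total RNA was isolated with the PureLink RNA Mini kit and libraries were made with the NEBNext Ultra RNA kit. The authors' table gives raw counts per gene symbol for 48 libraries and 27978 symbols, of which 4194 had 0 counts in every library. Per the submitters' processing notes the tools were Trim Galore 0.4.2, STAR 2.5.3a and edgeR with the genome build hg19; the counting tool, the annotation version and the strand setting are not stated there. Whole numbers in every cell and totals that differ between columns were checked before use. All 48 columns mapped to a sample, and none was left out. No replicate pair was identical: the chi-square per gene between replicates ran from 4.08 to 79.6.

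Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 16 groups with a minimum count of 10 and a minimum total of 15, which left 15789 genes holding 99.97% of counts. TMM factors, robust dispersion estimates (common biological coefficient of variation 0.102) and robust quasi-likelihood fits with 1 mean per group and 32 residual degrees of freedom were used. Each comparison was a contrast of this fit, tested two-sided with glmQLFTest and adjusted by the Benjamini-Hochberg method over all genes tested; genes with adjusted p under 0.05 are called. The SE of a log2 fold change is its size divided by the square root of the F statistic. The interactions tested the mean over the 4 dose pairs of the change with both agents minus the changes with each. CPM values are counts relative to library totals scaled by the TMM factors.

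Before the count files were opened, 25 gene lists, the comparisons, the alternatives and a rule for the named genes were fixed. The lists cover DNA replication, mitosis, homologous recombination and Fanconi repair, p53 targets, the ATF4 and CHOP stress response, endoplasmic reticulum chaperones, cholesterol synthesis, lysosome and autophagy, hypoxia and glycolysis, NRF2 antioxidant genes, aryl hydrocarbon receptor targets, EGFR to ERK output, receptor tyrosine kinases and ligands, apoptosis, interferon-stimulated genes, NF-kappaB cytokines, mesenchymal genes, drug efflux and metabolism, heat shock, ribosomal proteins, replication-dependent histones, and markers of luminal breast, alveolar and airway epithelium, blood cells and fibroblasts. They were tested with camera in limma 3.58.1 on voom values, two-sided, with a preset correlation between genes of 0.01 and again with an estimated one, adjusted over all lists in 6 main comparisons. Members that passed the count filter are the measured ones.

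In each main comparison the named genes are the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups. To these come the 3 members with the smallest p, in the list's direction, of each list with camera adjusted p under 0.05 (at most 8 lists), and EGFR, ERBB2, ERBB3, MET and AXL in the gefitinib comparisons. Elsewhere the 3 largest rises and falls by the same rule are named; an interaction needs no separation of libraries. A gene named in 1 comparison may be given its value in another. For liver and intestine transcripts absent from a whole group only counts are given.

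Alternatives planned beforehand were relative log expression factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, fits of only the 6 libraries compared or of the 27 libraries of an interaction, an F test of the 4 interaction terms together, adjusted p under 0.01, and each library left out in turn (48 fits). Alternatives added after seeing the data were library-size scaling, a batch term for libraries with over 1000 ALB counts, the lone library outside that batch, only library 3 of the 0 h group, a correction for the GC share of each gene's longest transcript, and the comparisons of each combination with its preparation alone. GC share and length came from reference transcripts matched by symbol, for 15196 of the genes tested (96.2%). Splits of 3 against 3 libraries were counted in edgeR fits of the 6 libraries (10 splits each). For the interactions, residuals of the fit without interaction terms were permuted over the libraries in 100 draws, the real one included, and tested with limma on log2 CPM. Slopes of the gefitinib response were taken over the genes called for gefitinib alone, each response against its own controls. Counts were also simulated for all 48 libraries, with changes set only in the 5 mg/mL YFSJ group and 15475 genes tested. Against untreated cells at 24 h, the test recovered 56 of 100 genes changed by 1.5-fold and 78 of 100 changed by 2-fold, with 3 false among 137 calls. The simulated noise was independent between genes, so it does not measure the error from deviations that genes of a library share.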

Results

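H1975 cells, a human non-small cell lung cancer line whose EGFR gene carries activating and resistance mutations, were treated with gefitinib, an inhibitor of the EGFR kinase, with 1 of 2 preparations, or with both. The preparations were CKI, compound kushen injection, and YFSJ, which the labels name only by these letters. RNA was sequenced from 48 libraries in 16 groups of 3, which the labels call biological replicates. Untreated cells were taken at 0 h and 24 h. The other 14 groups were gefitinib at 50 or 75 µM, CKI at 1 or 2 mg/mL, YFSJ at 2.5 or 5 mg/mL, and every pairing of a gefitinib dose with a dose of either preparation. The values were raw counts per gene symbol. Totals ran from 16428398 to 26264162 counts per library. A floor of 3 counts corresponded to 0.183 CPM in the smallest library and 0.114 CPM in the largest, covering counting error only. The libraries were unstranded, so values of genes that overlap another gene on the opposite strand are uncertain.

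The labels name the line H1975 and also give a catalogue number that belongs to MCF-7, a breast cancer line, so markers of both tissues were read. Median levels across the 48 libraries were 44.7 CPM for NKX2-1, a lung lineage transcription factor, 96.5 CPM for EGFR and 69.6 CPM for CDKN2A. The estrogen receptor gene ESR1 had a median of 0.125 CPM and at most 11 counts in any library. PGR and TFF3, both luminal breast genes, had a median of 0 CPM, and GATA3 had 0.681 CPM. Of the fixed marker lists, 8 of 23 alveolar and airway genes, 10 of 20 luminal breast genes, 3 of 20 blood cell genes and 6 of 16 fibroblast genes had a median of at least 1 CPM.

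The first principal component of log CPM held 35.9% of the variance and separated the gefitinib groups from the untreated groups and those with YFSJ alone. The second held 23.1% and rose with CKI, alone and with gefitinib. At 0 h, libraries 1 and 2 stood apart from library 3: mitochondrial RNR2 took 1.22% and 1.69% of their counts against 0.457%. Library 2 of 2.5 mg/mL YFSJ with 75 µM gefitinib also stood apart, with 2.18% of counts in RNR2. The RNR2 share also differed between treatments, from 0.464% to 0.582% in untreated cells at 24 h, 0.919% to 1.16% with 2 mg/mL CKI, 1.13% to 1.32% with 50 µM gefitinib added to it and 1.39% to 1.56% with 75 µM.

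**Figure D1:**
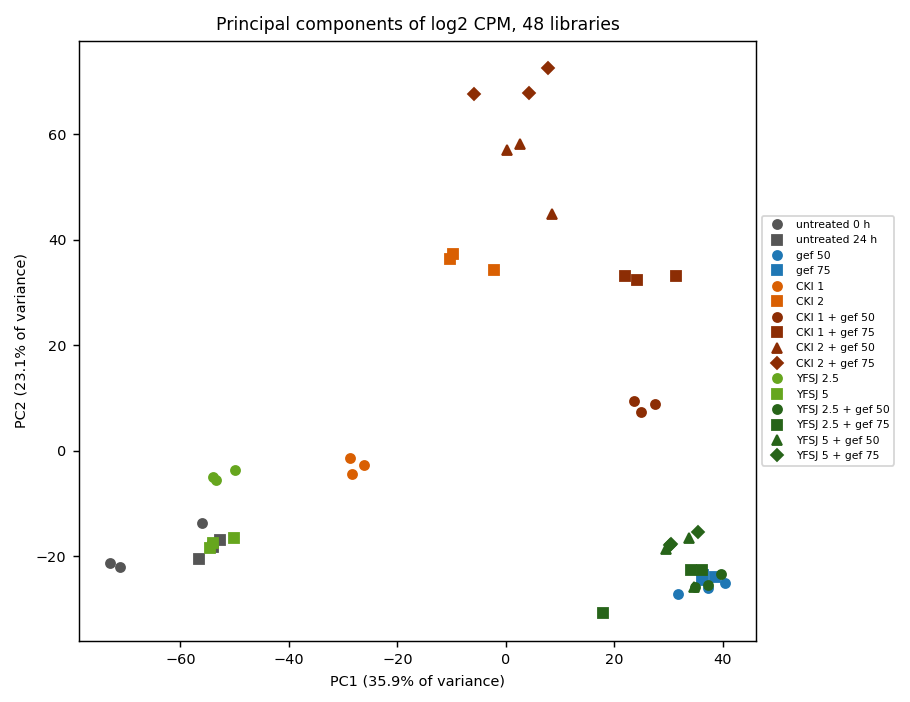
Principal components of log CPM for the 48 libraries, PC1 (35.9% of variance) on the horizontal axis and PC2 (23.1%) on the vertical axis, 1 point per library, marked by treatment. The groups of 2 mg/mL CKI with gefitinib lie highest on PC2.

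Transcripts of liver-secreted proteins marked a further set of 10 libraries. ALB, the gene of serum albumin, had 2581 to 3557 counts in these 10 and 0 to 8 counts in the other 38. The set held all 3 libraries of 2.5 mg/mL YFSJ, all 3 of 2 mg/mL CKI with 75 µM gefitinib, 2 of 3 of 2 mg/mL CKI with 50 µM gefitinib and 2 of 3 of 1 mg/mL CKI with 75 µM gefitinib. In it, 23 of 30 liver markers and 5 of 21 intestine markers were higher than in every other library, as were 0 of the kidney, pancreas, brain, muscle and blood cell markers. APOB, the gene of apolipoprotein B, had 362 to 521 counts there and 0 to 1 elsewhere. A fit with this set as a batch term was therefore added after the data were seen, and its counts are given for the comparisons that the set enters. The term is estimated only from the groups that hold libraries of both kinds. For groups that lie wholly in the set it also widens the error, so a lower count cannot tell a removed batch effect from lost precision.

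**Figure D2:**
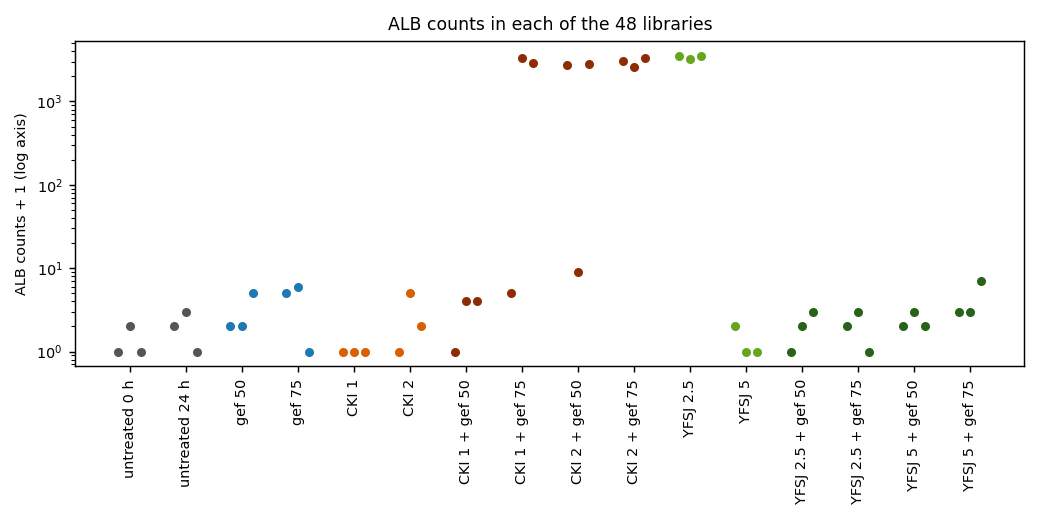
ALB counts plus 1, on a log axis, for each of the 48 libraries by group. The 10 libraries between 2581 and 3557 counts belong to 4 groups; all others have 0 to 8 counts.

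Untreated cells at 24 h were compared with those at 0 h for the change over the day in culture. Libraries 1 and 2 at 0 h stood apart from library 3, so the differences are not those of time alone. Fold changes are given throughout as log2 ± SE, with n = 3 libraries per group. The immediate early gene FOS rose by 2.55 ± 0.29 (adjusted p = 1.92e-07), ZFP36, which destabilises inflammatory mRNAs, by 1.36 ± 0.19 (adjusted p = 1.7e-06), and CRABP2, a retinoic acid carrier, by 1.46 ± 0.16 (adjusted p = 3.62e-08). SNHG19, ZNF767P and RSRP1 rose by 1.63, 1.61 and 1.52. SPRY4, a feedback inhibitor of growth factor signalling, fell by 1.64 ± 0.15 (adjusted p = 3.42e-10), the circadian deadenylase NOCT by 1.59 ± 0.16 (adjusted p = 5.39e-09), the matrix gene THBS1 by 1.5 ± 0.16 (adjusted p = 7.25e-09) and KRT17, a keratin, by 1.43 ± 0.16 (adjusted p = 7.69e-08). MYH16 and SPRED3 fell by 1.51 and 1.36.

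Gene lists fixed before the data were examined are given with the number of measured members called over all genes and, where it differs, the number adjusted over the list alone. Heat shock genes fell in 11 of 19 and rose in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 8.5e-05, and adjusted p = 0.0755 with an estimated correlation), among them the chaperones DNAJB1 (-0.55), HSPH1 (-0.56) and HSPA1A (-0.58). Hypoxia and glycolysis genes fell in 11 of 31 (13 down and 1 up adjusted over the list alone; adjusted p = 0.000151, and adjusted p = 0.0296 with an estimated correlation), including NDRG1 (-0.51), HK1 (-0.61) and SLC2A1 (-0.41). Of 21 mesenchymal genes 9 fell and 2 rose (adjusted p = 0.00121, and adjusted p = 0.08 with an estimated correlation), with LOX at -0.75 and ITGA5 at -0.49. Of 26 genes of EGFR to ERK output 10 fell and 2 rose (12 and 3 adjusted over the list alone; adjusted p = 0.00222, and adjusted p = 0.251 with an estimated correlation), with HBEGF at -0.97 and DUSP5 at -0.77. Of 21 receptor tyrosine kinase genes 7 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.00222, and adjusted p = 0.0996 with an estimated correlation), including AXL (-0.98), TYRO3 (-0.70) and IGF1R (-0.38). Of 34 ribosomal protein genes 8 rose (9 adjusted over the list alone; adjusted p = 0.00151, and adjusted p = 0.532 with an estimated correlation), among them RPS28 (0.54), RPLP2 (0.51) and RPLP1 (0.48). Of 31 interferon-stimulated genes 11 rose and 1 fell (13 and 2 adjusted over the list alone; adjusted p = 0.00238, and adjusted p = 0.26 with an estimated correlation), including IFI44 (0.70), OASL (0.65) and ISG15 (0.50). Of 26 cholesterol synthesis genes 7 fell and 1 rose (adjusted p = 0.0123, and adjusted p = 0.422 with an estimated correlation), with DHCR7 at -0.69. Of 26 NRF2 antioxidant genes 7 rose and 1 fell (7 and 2 adjusted over the list alone), at camera adjusted p = 0.0494. The list did not pass with relative log expression factors (adjusted p = 0.0548), with the replicate block (adjusted p = 0.0513) or with an estimated correlation (adjusted p = 0.381). Mitosis genes rose in 4 of 30 and fell in 4 (4 and 5 adjusted over the list alone; adjusted p = 0.962).

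In all, 3980 genes passed adjusted p < 0.05, 1708 higher and 2272 lower at 24 h. Of the calls, 42.9% were higher, and 62% with library-size scaling. A fit of only the 6 libraries called 93 genes. With only library 3 of the 0 h group, 147 genes passed, and of the named genes FOS, CRABP2, ZFP36, SPRY4, NOCT, MYH16, THBS1, KRT17, SPRED3, LOX, ITGA5, HBEGF, DUSP5 and OASL kept the call while the other genes given here lost it. Some effects also shrank against library 3 alone: AXL was at -0.05, TYRO3 at -0.16, DNAJB1 at -0.18, HSPA1A at -0.25 and RPLP2 at 0.15. Others hardly moved, with ISG15 at 0.50 and SLC2A1 at -0.37. The lists were not tested without libraries 1 and 2. Without library 1 or 3 of the 0 h group, or library 2 at 24 h, the count was 1070, 6029 or 2607. Without the first of these RPS28 (adjusted p = 0.0519), RPLP2 (adjusted p = 0.0678), IGF1R (adjusted p = 0.0575) and ISG15 (adjusted p = 0.0512) lost the call. ISG15 also lost it with a GC correction (0.41, adjusted p = 0.0574).

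Gefitinib at 75 µM was compared with untreated cells at 24 h for the response to the drug itself. Genes of cell division fell: CDC20, the activator of the anaphase-promoting complex, dropped from 390 ± 35 CPM (SD, n = 3) to 68.4 ± 4.41 CPM, a log2 fold change of -2.51 ± 0.09 (adjusted p = 5.39e-27), and CCNB1, the gene of cyclin B1, and KIF2C, a kinesin of the spindle, fell by 2.41 and 2.36. All 30 mitosis genes fell, with a median of -2.43 (camera adjusted p = 4.08e-36). Genes of sterol synthesis rose: LSS, the gene of lanosterol synthase, went from 72.4 ± 6.67 to 590 ± 33.2 CPM, by 3.03 ± 0.14 (adjusted p = 6.64e-23). CHAC1, a glutathione-degrading enzyme and ATF4 target, rose by 3.31 ± 0.15 (adjusted p = 1.82e-22).

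All 32 DNA replication genes fell, with a median of -2.08 (adjusted p = 8.62e-33), as did all 22 genes of homologous recombination and Fanconi repair, with a median of -1.94 (adjusted p = 1.72e-18). Members were the nucleotide reductase gene RRM2 (-2.90 ± 0.12), UHRF1 (-2.86 ± 0.11), MCM3 of the replicative helicase (-1.99 ± 0.07), EXO1 (-2.94 ± 0.12), FANCI (-2.18 ± 0.12) and RAD54L (-2.15 ± 0.12). The largest falls in the comparison were MCM10 (-3.69 ± 0.15, adjusted p = 1.42e-24), FAM111B (-3.37), E2F2 (-3.26), RGS4 (-3.26), NEIL3 (-3.18) and ERCC6L (-3.17). Of 29 genes of the ATF4 and CHOP stress response 27 rose (median 1.43, adjusted p = 2.99e-21), with SESN2 at 2.36 ± 0.10 and TRIB3 at 2.23 ± 0.10. Of 26 cholesterol synthesis genes 25 rose (median 1.34, adjusted p = 1.99e-17), including INSIG1 (2.27 ± 0.11), HMGCS1 (1.84 ± 0.11) and SQLE, the gene of squalene epoxidase (1.57 ± 0.08). Lysosome and autophagy genes rose in 29 of 37 and fell in 3 (30 and 3 adjusted over the list alone; median 0.64, adjusted p = 1.82e-11), with the proton pump subunit ATP6V0D2 at 3.27 ± 0.19, WIPI1 at 2.14 ± 0.12 and SQSTM1, an autophagy receptor, at 1.70 ± 0.09. These 6 lists also passed with an estimated correlation, at adjusted p = 0.000705 for mitosis, 1e-05 for replication, 0.00309 for repair, 7.09e-08 for ATF4 and CHOP, 0.00699 for cholesterol and 1e-05 for lysosome.

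Genes of EGFR to ERK output fell in 17 of 26 and rose in 1 (18 and 1 adjusted over the list alone; median -0.71, adjusted p = 0.000119, and adjusted p = 0.144 with an estimated correlation). FOSL1, a transcription factor downstream of ERK, fell by 2.21 ± 0.16 (adjusted p = 2.25e-15), DUSP6, the phosphatase that restrains ERK, by 1.27 ± 0.13 (adjusted p = 3.05e-11), PHLDA1 by 1.03 ± 0.09, SPRY4 by 0.89 ± 0.18, DUSP5 by 0.71 ± 0.12 and HBEGF by 0.56 ± 0.14. EGFR itself was at -0.03 ± 0.17 (adjusted p = 0.904; 0.06 with library-size scaling) and MET at -0.21 ± 0.13 (adjusted p = 0.174), while ERBB3 rose by 0.83 ± 0.12 (adjusted p = 5.41e-08), ERBB2 rose by 0.60 ± 0.11 (adjusted p = 9.8e-06) and AXL fell by 0.78 ± 0.20 (adjusted p = 0.000901). Heat shock genes fell in 14 of 19 and rose in 1 (median -0.57, adjusted p = 0.00101, and adjusted p = 0.134 with an estimated correlation), with CHORDC1 at -1.45, HSPA4 at -1.04 and DNAJA1 at -0.88. HSPA1A was at -0.20 ± 0.14 (adjusted p = 0.255), and at -0.47 (adjusted p = 0.00653) with a GC correction. Interferon-stimulated genes rose in 17 of 31 and fell in 8 (median 0.44, adjusted p = 0.00538, and adjusted p = 0.304 with an estimated correlation), with the antiviral genes OAS2 and IFI44L at 1.58 ± 0.16 and 1.38 ± 0.18. Targets of p53 rose in 12 of 22 and fell in 4 (12 and 5 adjusted over the list alone; adjusted p = 0.0267, and adjusted p = 0.0671 with an estimated correlation). Targets of the aryl hydrocarbon receptor rose in 6 of 11 and fell in 1 (adjusted p = 0.0186, and adjusted p = 0.226 with an estimated correlation), with CYP1A1, a monooxygenase of foreign compounds, at 1.13 ± 0.30. The stress cytokine gene GDF15 rose by 3.23 ± 0.23.

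The largest rises were KLHDC7B (5.41 ± 0.28, adjusted p = 1.24e-18), the endogenous retroviral gene ERVV-2 (4.33 ± 0.26), ADM2, a peptide hormone gene (4.12 ± 0.16, adjusted p = 3.84e-25), LOC100130705 (4.01), IGFL2-AS1 (3.91) and the transcription factor MAF (3.89 ± 0.22). The lists of other receptor tyrosine kinases (9 up and 5 down of 21, adjusted p = 0.451), apoptosis (12 and 4 of 29, adjusted p = 0.113) and NF-kappaB cytokines (9 and 3 of 23, adjusted p = 0.0661) did not pass. In all, 8637 genes passed, 4360 higher and 4277 lower.

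At 50 µM the pattern was alike: KLHDC7B rose by 4.95 ± 0.29, ERVV-2 by 4.30 ± 0.26 and MAF by 4.07 ± 0.22, and MCM10, E2F2 and RGS4 were at -3.70 ± 0.15, -3.49 ± 0.22 and -3.25 ± 0.16. All 30 mitosis and all 32 replication genes fell, and 25 of 26 cholesterol and 27 of 29 ATF4 and CHOP genes rose. In all 8597 genes passed, 4364 higher and 4233 lower. Of the calls, 50.8% were higher, and 61.1% with library-size scaling, which shifted the median of all genes by 0.105. Between 75 and 50 µM, 5 genes passed, all higher at 75 µM and all interferon-stimulated: OAS2 by 1.16 ± 0.16 (adjusted p = 6.21e-05), MX1 by 1.06 ± 0.15 (adjusted p = 7.46e-05), IFI44L by 1.04 ± 0.18 (adjusted p = 0.00219), and MX2 (0.67) and OAS1 (0.64), the last pair chosen after the values were seen; 17 of 31 interferon-stimulated genes passed adjusted over the list alone. Without library 3 at 75 µM 2 genes passed, and IFI44L did not (0.87, adjusted p = 0.168).

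**Figure D3:**
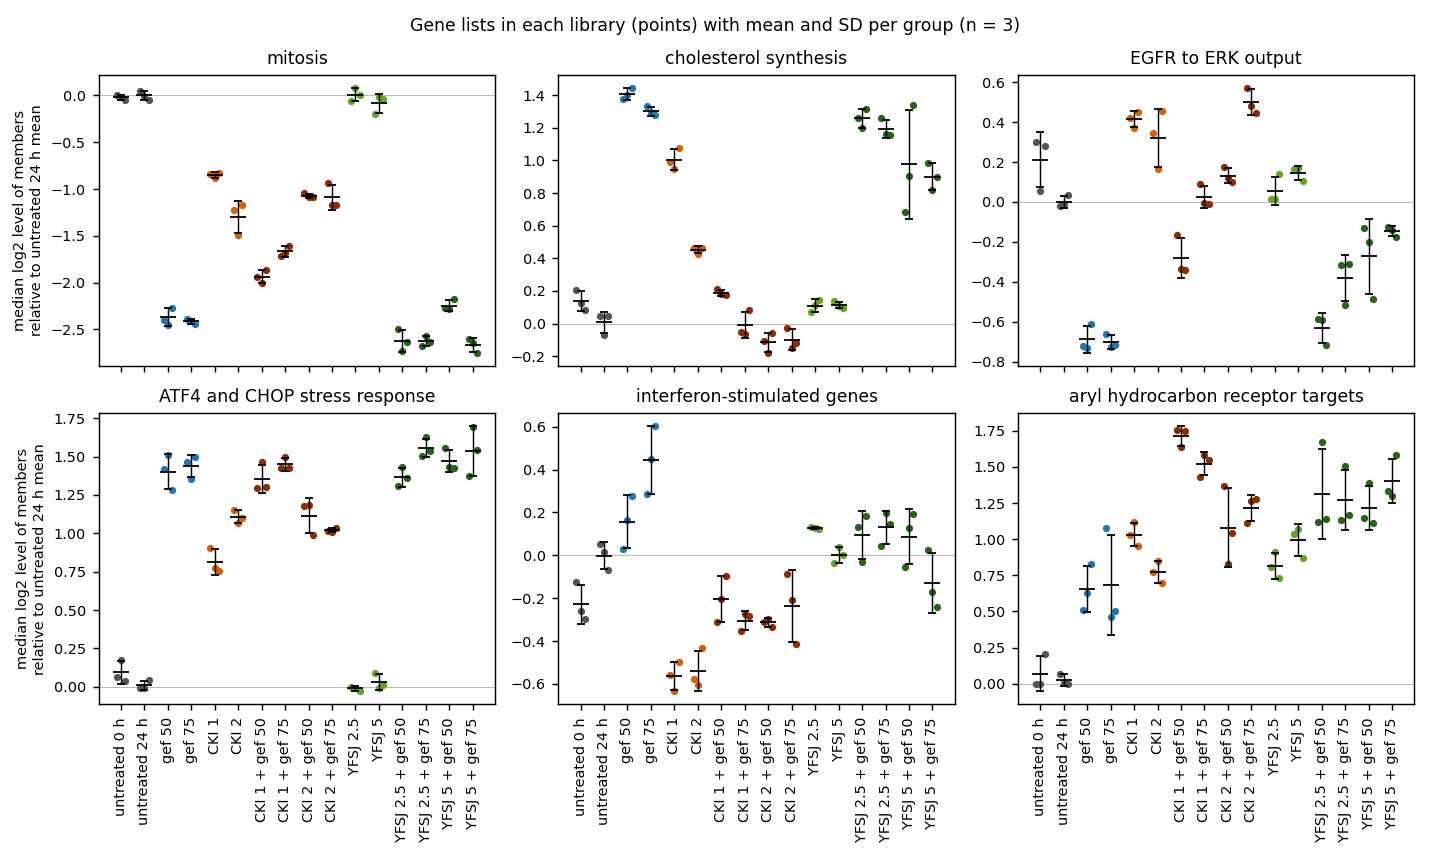
Median log2 level of 6 fixed gene lists relative to untreated cells at 24 h, by group, with 1 point per library and the mean ± SD of 3. Mitosis genes lie at -2.42 with 75 µM gefitinib, -1.30 with 2 mg/mL CKI and -1.09 with both.

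CKI at 2 mg/mL was compared with untreated cells at 24 h for the effect of the preparation by itself. HSPA6, a chaperone gene that is almost silent without proteotoxic stress, rose from 2.20 ± 0.52 to 126 ± 14.5 CPM (SD, n = 3), by 5.86 ± 0.17 (adjusted p = 4.46e-29). NGFR, a neurotrophin receptor gene, rose by 5.88 ± 0.29 (adjusted p = 5.73e-21), GDF15 by 4.86 ± 0.24 (adjusted p = 1.7e-18), the cytokine gene IL24 by 4.37 ± 0.28, GCNT3 by 4.27 ± 0.30 and RRAGD, a GTPase of lysosomal nutrient sensing, by 4.26 ± 0.23. CYP1A1 rose by 4.23 ± 0.23 (adjusted p = 2.74e-19). The largest falls were DIO2, an enzyme that activates thyroid hormone (-2.62 ± 0.23), RASSF10 (-2.54), TNS4 (-2.39), CYP24A1, which inactivates vitamin D (-2.39 ± 0.15), E2F8 (-2.38) and FAM111B (-2.38).

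The cell cycle lists fell here too: all 30 mitosis genes (median -1.28, adjusted p = 3.15e-27), 31 of 32 replication genes (median -1.15, adjusted p = 5.68e-24) and 21 of 22 repair genes (adjusted p = 7.5e-12). Examples were KIF20A (-1.96 ± 0.11), AURKA (-1.35 ± 0.08), CCNB1 (-1.32 ± 0.09), CDC20 (-1.15 ± 0.08), UHRF1 (-2.06), RRM2 (-1.93), MCM3 (-1.77), RMI2 (-1.31), FANCI (-1.25) and EXO1 (-1.20). Of 29 ATF4 and CHOP genes 26 rose and 1 fell (median 1.12, adjusted p = 9.14e-22), with SLC7A11, the cystine importer, at 3.93 ± 0.16, ATF3 at 3.66 ± 0.16, CHAC1 at 3.21 ± 0.15 and SESN2 at 2.75 ± 0.10. NRF2 antioxidant genes rose in 15 of 26 and fell in 3 (median 0.65, adjusted p = 1.68e-06), with SRXN1 at 1.35 and TRIM16L at 1.16, while NQO1 was at 0.03 ± 0.09 (adjusted p = 0.831), and at 0.23 (adjusted p = 0.0342) with library-size scaling. Lysosome and autophagy genes rose in 23 of 37 and fell in 1 (median 0.41, adjusted p = 2.43e-07), with ATP6V0D2 at 3.10 and GABARAPL1 at 1.92. Targets of p53 rose in 14 of 22 and fell in 3 (median 0.42, adjusted p = 0.000125). Mesenchymal genes fell in 13 of 21 and rose in 1 (median -0.70, adjusted p = 9.16e-05). With an estimated correlation these lists passed at adjusted p = 0.00288, 9.66e-05, 0.0182, 7.09e-08, 0.0307, 0.000368, 0.00241 and 0.0307 in the order given.

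Other lists passed only with the preset correlation. Ribosomal protein genes fell in 30 of 34 (31 adjusted over the list alone; median -0.34, adjusted p = 6.37e-06, and adjusted p = 0.359 with an estimated correlation), with RPS6, RPS23 and RPL5 at -0.47, -0.43 and -0.39. Cholesterol synthesis genes rose in 17 of 26 and fell in 1 (median 0.45, adjusted p = 9.73e-06, and adjusted p = 0.16 with an estimated correlation), with TM7SF2 at 2.45 ± 0.20, MSMO1 at 1.25 ± 0.12 and INSIG1 at 1.12 ± 0.10. Interferon-stimulated genes fell in 22 of 31 and rose in 3 (median -0.53, adjusted p = 6.59e-05, and adjusted p = 0.134 with an estimated correlation), with IFI44L at -1.24 ± 0.21. Genes of EGFR to ERK output rose in 13 of 26 and fell in 3 (median 0.27, adjusted p = 0.00151, and adjusted p = 0.226 with an estimated correlation), with DUSP6 at 0.76 ± 0.12. Endoplasmic reticulum chaperones rose in 14 of 23 and fell in 4 (adjusted p = 0.000465, and adjusted p = 0.211 with an estimated correlation). Aryl hydrocarbon receptor targets rose in 6 of 11 and fell in 1 (adjusted p = 0.00118, and adjusted p = 0.0971 with an estimated correlation). Apoptosis genes rose in 15 of 29 and fell in 3 (adjusted p = 0.00228, and adjusted p = 0.0776 with an estimated correlation), and NF-kappaB cytokine genes rose in 12 of 23 and fell in 4 (13 and 4 adjusted over the list alone; adjusted p = 0.00199, and adjusted p = 0.321 with an estimated correlation). Replication-dependent histone genes fell in 11 of 20 (adjusted p = 0.00312, and adjusted p = 0.16 with an estimated correlation), and fibroblast genes fell in 3 of 7 (adjusted p = 0.0486, and adjusted p = 0.263 with an estimated correlation).

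Heat shock genes rose in 8 of 19 and fell in 8, with HSPA1A at 0.84 ± 0.14 and DNAJB1 at 0.64 ± 0.10. Among receptors AXL fell by 1.06 ± 0.20 (adjusted p = 2.45e-05), ERBB3 was at 0.04 ± 0.12 (adjusted p = 0.787) and MET at -0.07 ± 0.13 (adjusted p = 0.706; 0.14 with library-size scaling). EGFR was at 0.37 ± 0.17 (adjusted p = 0.055), and passed at 0.58 (adjusted p = 0.00431) with library-size scaling, at 0.39 (adjusted p = 0.0333) with DESeq2, at 0.39 (adjusted p = 0.044) with relative log expression factors and at 0.39 (adjusted p = 0.0311) with a GC correction. ERBB2 fell by 0.38 ± 0.11 (adjusted p = 0.00344), and was at -0.18 (adjusted p = 0.129) with library-size scaling. In all, 8086 genes passed, 3807 higher and 4279 lower. Of the calls, 47.1% were higher, and 69% with library-size scaling, which shifted the median of all genes by 0.201.

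At 1 mg/mL CKI the largest rises were CYP1A1 (4.82 ± 0.23, adjusted p = 9.85e-21), IL24 (4.10 ± 0.28) and SLC7A11 (3.45 ± 0.16), and the largest falls were the semaphorin gene SEMA5B (-2.68 ± 0.40), LYPD1 (-2.61 ± 0.23) and DIO2 (-2.44 ± 0.23). GDF15 and NGFR rose by 3.18 ± 0.23 and 2.18 ± 0.38, and HSPA6 was at 0.22 ± 0.22 (adjusted p = 0.488). All 30 mitosis genes (median -0.84) and 30 of 32 replication genes fell, 27 of 29 ATF4 and CHOP genes rose (28 adjusted over the list alone), 25 of 26 cholesterol genes rose (median 1.01), 21 of 26 NRF2 genes rose (22 adjusted over the list alone; median 0.91) and 19 of 31 interferon-stimulated genes fell (21 adjusted over the list alone). In all 4401 genes passed, 2078 higher and 2323 lower. Of the calls, 47.2% were higher, and 64.5% with library-size scaling.

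Between 2 and 1 mg/mL CKI, HSPA6 was higher at 2 mg/mL by 5.63 ± 0.17 (adjusted p = 4.53e-29), the activity-induced gene ARC by 3.73 ± 0.18 and NGFR by 3.69 ± 0.22. HNRNPA1P33, ARNT2, a partner of the aryl hydrocarbon receptor, and the laminin gene LAMB1 were lower, at -1.70 ± 0.19, -1.63 ± 0.16 and -1.58 ± 0.15. CYP1A1 was lower at the higher dose (-0.59 ± 0.16, adjusted p = 0.00355), as were 20 of 26 cholesterol genes, 16 of 26 NRF2 genes and 23 of 30 mitosis genes (22, 18 and 25 adjusted over the list alone), while 16 of 29 ATF4 and CHOP genes were higher (17 adjusted over the list alone). CDC20 was at -0.11 ± 0.08 (adjusted p = 0.297), and at 0.01 with library-size scaling. In all 5162 genes passed, 2389 higher and 2773 lower. Of the calls, 46.3% were higher, and 69.9% with library-size scaling, which shifted the median by 0.117.

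YFSJ at 5 mg/mL was compared with untreated cells at 24 h in the same way and changed fewer genes. CYP1A1 rose from 0.969 ± 0.347 to 11.4 CPM, by 3.51 ± 0.24 (adjusted p = 1.01e-14). ICAM1, an adhesion molecule under NF-kappaB control, rose by 1.56 ± 0.11 (adjusted p = 1.01e-14), SECTM1 by 2.21 ± 0.22 (adjusted p = 2.6e-09), C1QTNF1 by 1.67 ± 0.15, SLC37A2 by 1.62 ± 0.16 and the chemokine CXCL1 by 1.41 ± 0.28 (adjusted p = 0.00091). FOS fell from 74.1 ± 8.69 to 14.5 CPM, by 2.36 ± 0.28 (adjusted p = 6.42e-07), a level near the 12.7 ± 2.48 CPM of untreated cells at 0 h. DUSP1, a phosphatase of MAP kinases, fell by 1.56 ± 0.13 (adjusted p = 1.36e-11), the endothelin gene EDN1 by 1.34 ± 0.17, ID2 by 1.20 ± 0.23, HES1 by 1.15 ± 0.16 and CGB5 by 1.09 ± 0.23.

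Of 11 aryl hydrocarbon receptor targets 8 rose (median 1.08, adjusted p = 9.52e-19), with CYP1B1 at 1.38 ± 0.11, STC2 at 1.28 ± 0.10 and TIPARP, a feedback repressor of the receptor, at 1.12 ± 0.13. NF-kappaB cytokine genes rose in 11 of 23 and fell in 1 (14 and 1 adjusted over the list alone; median 0.66, adjusted p = 2.27e-11), with BIRC3 at 2.18 ± 0.24 and RELB at 1.26 ± 0.16, while CXCL8 and PTGS2 were at 0.95 ± 0.38 (adjusted p = 0.138) and 0.55 ± 0.24 (adjusted p = 0.163), PTGS2 passing at 0.70 (adjusted p = 0.031) with a GC correction. NRF2 antioxidant genes rose in 8 of 26 (12 adjusted over the list alone; adjusted p = 1.24e-08), with SLC7A11 at 1.22 and HMOX1 and TRIM16L both at 0.51. Replication-dependent histones fell in 5 of 20 (10 adjusted over the list alone; median -0.44, adjusted p = 4.02e-06), with HIST1H2BC at -0.79, HIST2H2BE at -0.67 and HIST1H2AE at -0.62. Lysosome and autophagy genes rose in 7 of 37 (13 up and 2 down adjusted over the list alone; adjusted p = 6.92e-05), with SQSTM1 at 0.60, ATP6V0A1 at 0.44 and NPC1 at 0.37. With an estimated correlation these 5 lists passed at adjusted p = 2.92e-05, 0.0267, 0.0113, 0.0259 and 0.00378 in the order given.

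Ribosomal protein genes fell in 6 of 34 (15 adjusted over the list alone; median -0.22, adjusted p = 5.45e-10, and adjusted p = 0.213 with an estimated correlation), with RPL38 at -0.44 and RPL23 at -0.37. Hypoxia and glycolysis genes rose in 6 of 31 and fell in 1 (adjusted p = 0.00564, and adjusted p = 0.119 with an estimated correlation), with the angiogenic factor VEGFA at 0.95 ± 0.12, NDRG1 at 0.68 and PFKFB3 at 0.46. Cholesterol synthesis genes rose in 4 of 26 (5 up and 1 down adjusted over the list alone; adjusted p = 0.00588, and adjusted p = 0.381 with an estimated correlation), with DHCR7 at 0.45 and SREBF2 at 0.37. Mesenchymal genes fell in 4 of 21 and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0336, and adjusted p = 0.251 with an estimated correlation). No call was made for any of the 30 mitosis genes (adjusted p = 0.161). CDC20 was at -0.01 ± 0.08 (adjusted p = 0.96) and EGFR at 0.30 ± 0.16 (adjusted p = 0.3). IL24 rose by 1.42 ± 0.32 (adjusted p = 0.00509). In all, 1023 genes passed, 675 higher and 348 lower. Without untreated library 1 or 2 the count was 555 or 407, and without YFSJ library 1 or 3 it was 419 or 598. RPL23, RPL38, HIST2H2BE, HIST1H2BC, HIST1H2AE, DHCR7 and SREBF2 each lost the call without at least 1 library, at adjusted p up to 0.116 for SREBF2.

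With 2.5 mg/mL YFSJ, CYP1A1 rose by 2.84 ± 0.25 (adjusted p = 6.73e-11), SECTM1 by 1.67 ± 0.23 and ICAM1 by 1.12 ± 0.11, and FOS and DUSP1 fell by 1.95 ± 0.27 and 1.63 ± 0.13. LOC284454 fell by 1.21 ± 0.26 (adjusted p = 0.00445), and was at -1.27 with adjusted p = 0.169 in the fit with the batch term. Of the lists, 8 of 11 aryl hydrocarbon receptor targets rose (8 up and 1 down adjusted over the list alone), and 5 of 23 NF-kappaB genes rose and 1 fell (11 and 2 adjusted over the list alone). In all 463 genes passed, 318 higher and 145 lower, with 68.7% of calls higher, and 83.3% with library-size scaling. All 3 libraries belong to the set with liver transcripts, and ALB and PIGR were among the largest rises. With the batch term, estimated only from other groups, 48 genes passed, 31 higher and 17 lower, so the drop may be lost precision. Without untreated library 1, 2 or 3 the count was 267, 168 or 262, and without YFSJ library 1 or 3 it was 243 or 162. LOC284454 lost the call without the last (adjusted p = 0.0543).

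Between 5 and 2.5 mg/mL YFSJ, 3 genes were higher at 5 mg/mL and 56 lower. ICAM1 was higher by 0.44 ± 0.10 (adjusted p = 0.025). ACTA1 (2.58, to a mean of 1.11 CPM) and MYH2 (to a mean of 1.13 CPM), both muscle genes, were named after the values were seen. ALB, PIGR and FGB led the lower genes and belong to the liver and intestine transcripts of the 2.5 mg/mL libraries. With the batch term, estimated only from other groups, 0 genes passed in edgeR, with 397 at an unadjusted p under 0.05. ICAM1 was then at 0.41, so the drop may be lost precision. ICAM1 lost the call without any 1 of the 6 libraries (adjusted p up to 0.261), with library-size scaling (adjusted p = 0.0683) and with a GC correction (adjusted p = 0.0626), and the count was 32 without 2.5 mg/mL library 1 and 24, 18 and 22 without 5 mg/mL libraries 1, 2 and 3.

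**Figure D4:**
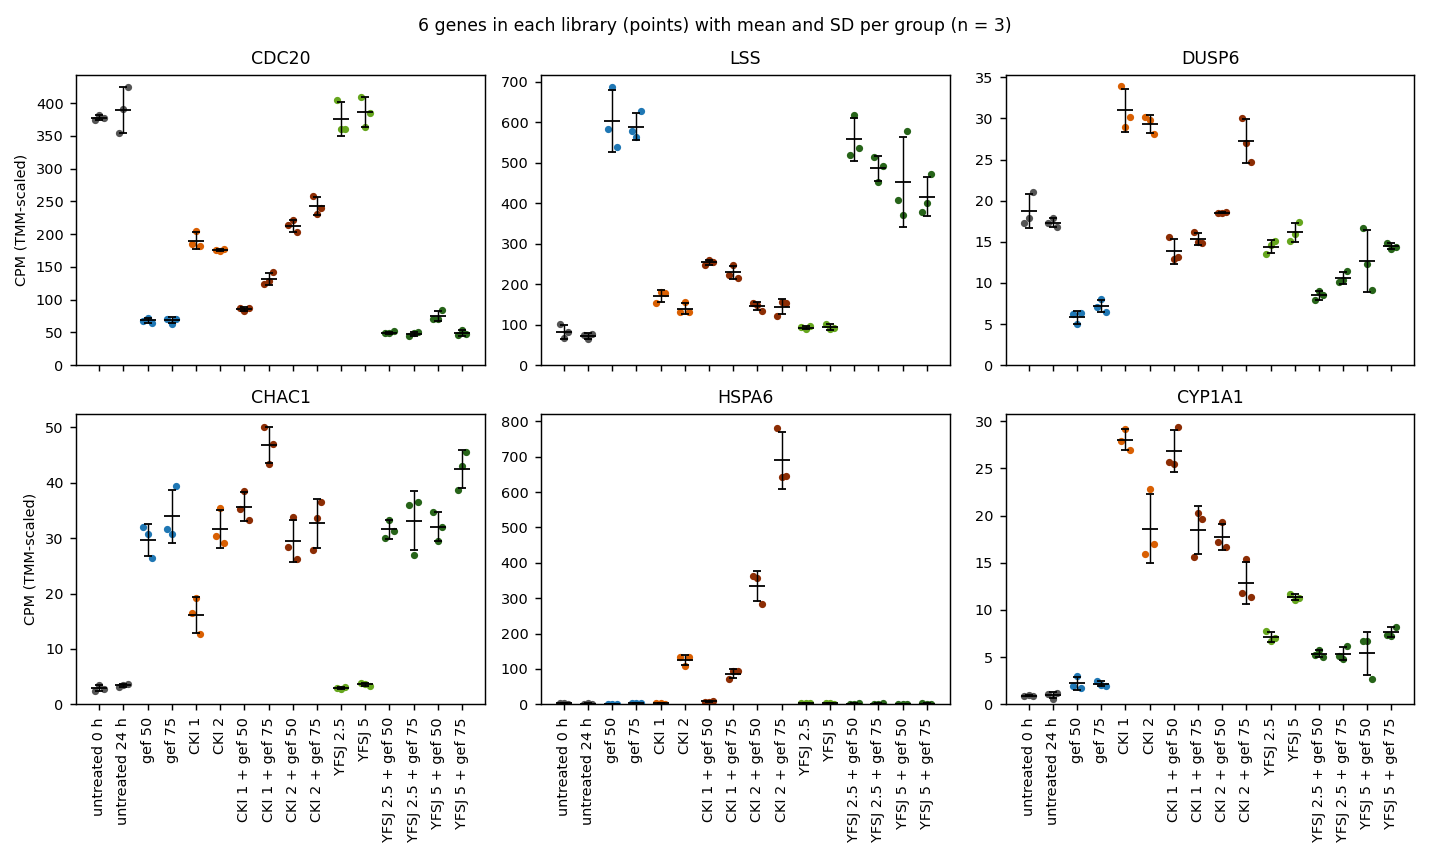
CPM of CDC20, LSS, DUSP6, CHAC1, HSPA6 and CYP1A1 by group, with 1 point per library and the mean ± SD of 3. HSPA6 reaches 690 ± 80 CPM with 2 mg/mL CKI and 75 µM gefitinib, and LSS 590 ± 33.2 CPM with 75 µM gefitinib.

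Between the preparations, 2 mg/mL CKI and 5 mg/mL YFSJ differed most in NGFR (6.18 ± 0.29), HSPA6 (5.76 ± 0.17) and the phosphatase gene DUSP15 (4.94 ± 0.29), all higher with CKI, and in the chemokine CCL2 (-3.25 ± 0.38), CEMIP (-2.82 ± 0.20) and NFE2 (-2.43 ± 0.25), all lower. CDC20 was lower with CKI (-1.14 ± 0.08, adjusted p = 2.22e-15), as were all 30 mitosis genes, and 24 of 29 ATF4 and CHOP genes were higher. CYP1A1 was higher by 0.72 ± 0.16 (adjusted p = 0.000309). In all 8014 genes passed, 3802 higher and 4212 lower. Of the calls, 47.4% were higher, and 68.8% with library-size scaling, which shifted the median by 0.197. The doses are not matched in any unit of activity.

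Adding 2 mg/mL CKI to 75 µM gefitinib, the question the series title raises, was tested against 75 µM gefitinib alone. CDC20 was higher with the pair, at 243 ± 14.3 against 68.4 ± 4.41 CPM (SD, n = 3), by 1.83 ± 0.09 (adjusted p = 9.82e-22), as were AURKB (1.70 ± 0.10) and KIF2C (1.43 ± 0.09). All 30 mitosis genes rose (median 1.29, adjusted p = 3.05e-20). LSS was at 144 ± 19 CPM against 590 ± 33.2, and the sterol genes HMGCS1, MSMO1 and SQLE fell by 2.40 ± 0.11, 1.95 ± 0.12 and 1.72 ± 0.08. HSPA6 reached 690 ± 80 CPM, a rise of 8.13 ± 0.18 (adjusted p = 2e-34), and HSPA1B, HSPA1A and DNAJB1 rose by 2.52 ± 0.17, 2.38 ± 0.14 and 1.99 ± 0.11.

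Of 26 cholesterol synthesis genes 24 fell (median -1.42, adjusted p = 1.9e-18). Of 32 replication genes 29 rose (30 adjusted over the list alone; median 0.99, adjusted p = 2.31e-14), with CDC6 at 1.99 ± 0.11, ORC6 at 1.88 ± 0.13 and GINS2 at 1.59 ± 0.11. Of 26 genes of EGFR to ERK output 24 rose (median 1.14, adjusted p = 4.54e-11), with SPRY4 at 2.53 ± 0.16, DUSP5 at 2.45 ± 0.12 and HBEGF, an EGFR ligand, at 2.37 ± 0.13. Heat shock genes rose in 14 of 19 and fell in 1 (median 0.71, adjusted p = 2.78e-07). With an estimated correlation mitosis and these lists passed, at adjusted p = 0.0101, 0.00532, 0.00244, 0.0107 and 0.0182 in the order given. Repair genes rose in 19 of 22 and fell in 1 (adjusted p = 1.21e-06, and adjusted p = 0.0996 with an estimated correlation), with EXO1 at 2.07, RAD54L at 1.60 and FANCA at 1.14. Endoplasmic reticulum chaperones rose in 19 of 23 (median 0.54, adjusted p = 4.02e-06, and adjusted p = 0.0971 with an estimated correlation), with DNAJB9 at 2.10 ± 0.16, MANF at 1.14 ± 0.11 and DNAJB11 at 0.81 ± 0.08. Interferon-stimulated genes fell in 20 of 31 and rose in 7 (21 and 7 adjusted over the list alone; median -0.77, adjusted p = 0.00013, and adjusted p = 0.152 with an estimated correlation), with IFI44L at -2.84 ± 0.20, MX2 at -2.10, IFI35 at -1.68 and IRF9 at -1.56. NF-kappaB genes rose in 16 of 23 and fell in 3 (adjusted p = 0.00151, and adjusted p = 0.304 with an estimated correlation), and apoptosis genes rose in 16 of 29 and fell in 5 (adjusted p = 0.0213, and adjusted p = 0.173 with an estimated correlation). Histones fell in 10 of 20 and rose in 5 (adjusted p = 0.0295, and adjusted p = 0.3 with an estimated correlation), and fibroblast genes fell in 4 of 7 and rose in 1 (adjusted p = 0.044, and adjusted p = 0.259 with an estimated correlation). The ATF4 and CHOP list (8 up and 17 down of 29, adjusted p = 0.124) and the lysosome list (8 up and 21 down of 37, adjusted p = 0.055) did not pass.

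The largest falls were LOC100286925 (-3.23), WISP2 (-3.12 ± 0.24), EPSTI1, an interferon-induced gene (-3.01 ± 0.28), the natriuretic peptide receptor NPR1 (-2.91 ± 0.15) and NKAIN4 (-2.90). Among genes raised by gefitinib, ERVV-2 fell by 2.26 ± 0.20, KLHDC7B by 1.09 ± 0.20 and MAF by 0.77 ± 0.16, and among those lowered by it MCM10 rose by 1.95 ± 0.15 and E2F2 by 1.46 ± 0.25. Genes raised by CKI alone were also higher in the pair: NGFR by 5.18 ± 0.28, CYP1A1 by 2.56 ± 0.21, SLC7A11 by 1.75 ± 0.14, IL24 by 1.62 ± 0.25 and GDF15 by 1.38 ± 0.20. ERBB2 fell by 0.79 ± 0.11 (adjusted p = 5.22e-08), and EGFR (-0.09 ± 0.17, adjusted p = 0.656), ERBB3 (-0.25 ± 0.11, adjusted p = 0.0536), MET (-0.25 ± 0.13, adjusted p = 0.111) and AXL (-0.31 ± 0.20, adjusted p = 0.177) did not pass. MET passed with a GC correction (adjusted p = 0.021). ERBB3 passed with the replicate block (adjusted p = 0.0472), without gefitinib library 2 (-0.29, adjusted p = 0.0496) and without combination library 3 (-0.31, adjusted p = 0.0367). In all, 9190 genes passed, 4549 higher and 4641 lower. All 3 libraries of the pair belong to the set with liver transcripts, and APOB, HP, PIGR, FGA and FGB were among the largest rises, with 0 to 8 ALB and 0 to 1 APOB counts outside the set. With the batch term 6911 genes passed, 3433 higher and 3478 lower.

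At 2 mg/mL CKI with 50 µM gefitinib, HSPA6 rose by 7.75 ± 0.18 (adjusted p = 4.07e-33) and CDC20 by 1.64 ± 0.08, while SQLE was at -1.81 ± 0.08, WISP2 at -3.35 ± 0.24, LOC100286925 at -2.80 ± 0.28 and NKAIN4 at -2.72 ± 0.26. All 30 mitosis genes rose and 25 of 26 cholesterol genes fell. In all 8468 genes passed, 4196 higher and 4272 lower, with 49.6% of calls higher, and 60.1% with library-size scaling. With only the library outside the liver-transcript set 5634 genes passed, 3065 higher and 2569 lower, and with the batch term 7237.

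At 1 mg/mL CKI with 50 µM gefitinib, IL24 rose by 4.40 ± 0.25, the protease gene HTRA3 by 3.63 ± 0.29, CYP1A1 by 3.59 ± 0.20 and HSPA6 by 2.40 ± 0.20, and SEMA5B, EFNA2 and SLCO2A1 were at -3.21 ± 0.34, -2.81 ± 0.29 and -2.66 ± 0.18. Mitosis genes rose in 22 of 30 (25 adjusted over the list alone) and cholesterol genes fell in 24 of 26. In all 5015 genes passed, 2453 higher and 2562 lower. Of the calls, 48.9% were higher, and 71% with library-size scaling, which shifted the median by 0.127. With 75 µM gefitinib, HSPA6 rose by 5.13 ± 0.17 (adjusted p = 5.46e-27), IL24 by 3.75 ± 0.25 and CYP1A1 by 3.08 ± 0.21, and SEMA5B, the hypoxia-linked RNA MIR210HG and NKAIN4 fell by 3.11 ± 0.33, 2.96 ± 0.29 and 2.87 ± 0.27. Mitosis genes rose in 29 of 30 (30 adjusted over the list alone), and 24 of 26 cholesterol and 22 of 31 interferon-stimulated genes fell. In all 5456 genes passed, 2724 higher and 2732 lower. Of the calls, 49.9% were higher, and 66.9% with library-size scaling, and 4435 genes passed with the batch term. PIGR, TF (5.63) and RMRP (5.59) headed the rises through the libraries with liver transcripts. With the lone other library TF was at 2.54 (adjusted p = 0.168) and RMRP at 0.83 (adjusted p = 0.799).

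How much of the gefitinib response remained beside each preparation was measured as a slope. The response with the preparation present was regressed on the response without it across the genes called for gefitinib alone (8637 at 75 µM, 8597 at 50 µM), with no library entering both responses. With 75 µM gefitinib the slope was 0.105 (SD 0.076, n = 3) with 2 mg/mL CKI, 0.509 (SD 0.031) with 1 mg/mL CKI, 0.818 (SD 0.039) with 5 mg/mL YFSJ and 0.798 (SD 0.074) with 2.5 mg/mL YFSJ. With 50 µM it was 0.113 (SD 0.030), 0.488 (SD 0.021), 0.841 (SD 0.042) and 0.882 (SD 0.024). By list, the median response of mitosis genes to 75 µM gefitinib was -2.43 alone, 0.18 with 2 mg/mL CKI, -0.86 with 1 mg/mL CKI and -2.57 with 5 mg/mL YFSJ. For cholesterol synthesis it was 1.34 alone, -0.47 with 2 mg/mL CKI, -0.93 with 1 mg/mL CKI and 0.77 with 5 mg/mL YFSJ. For genes of EGFR to ERK output it was -0.71 alone, 0.11 with 2 mg/mL CKI, -0.37 with 1 mg/mL CKI and -0.18 with 5 mg/mL YFSJ. The slope over these 26 genes was -0.023 with 2 mg/mL CKI and 0.53 with 1 mg/mL CKI. It was 0.629 with 5 mg/mL YFSJ and 0.774 with 2.5 mg/mL YFSJ. Genes are not independent replicates, and the SD is over the 3 libraries.

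**Figure D5:**
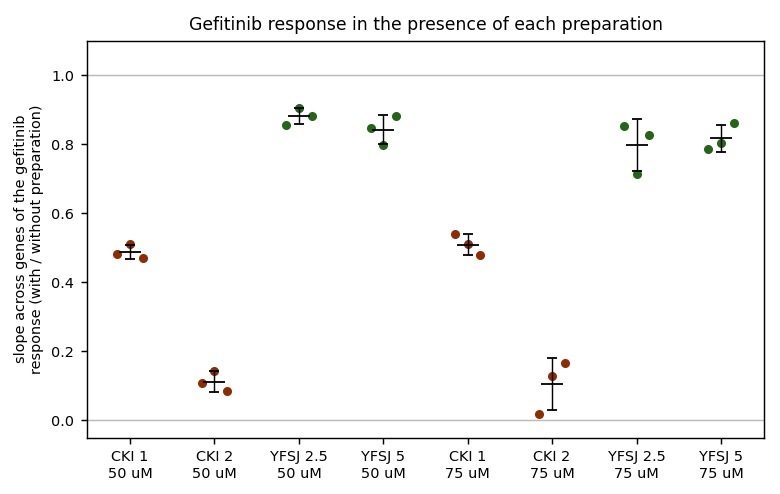
Slope across genes of the gefitinib response with a preparation on the response without it, for each preparation, its dose and the gefitinib dose, with 1 point per library and the mean ± SD of 3. Lines mark 0 and 1. With 2 mg/mL CKI the means are 0.113 and 0.105.

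Whether CKI and gefitinib acted additively on log levels was tested as an interaction over all dose pairs. CDC20 had an interaction of 2.28 ± 0.09 (adjusted p = 9.08e-25), E2F2 of 3.18 ± 0.22 and HSPA6 of 2.81 ± 0.24, each above the sum of the separate effects. ERVV-2 (-4.09 ± 0.28), KLHDC7B (-3.56 ± 0.31), TM7SF2 (-3.50 ± 0.21), LSS (-2.77 ± 0.14), CHAC1 (-2.55 ± 0.16) and SQLE (-2.47 ± 0.09) lay below it, and DUSP6 lay above by 0.69 ± 0.13 (adjusted p = 3.81e-05). All 30 mitosis (median 2.05), all 32 replication (median 1.69) and all 22 repair genes were above, as were 14 of 26 genes of EGFR to ERK output (15 adjusted over the list alone) and 13 of 19 heat shock genes. Of the lists, 25 of 26 cholesterol genes (median -2.15), 26 of 29 ATF4 and CHOP genes (median -1.01) and 29 of 37 lysosome genes were below. In all 6237 genes passed, 3158 above and 3079 below, and 5206 with the batch term. RPPH1, a noncoding RNA raised in the liver-transcript libraries, was at 3.98 ± 1.26 (adjusted p = 0.0119) and, with the batch term, at 1.51 (adjusted p = 0.231).

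Adding 5 mg/mL YFSJ to 75 µM gefitinib was tested in the same way. The interferon-stimulated genes IFI44L, OAS2, IFIT1 and IRF9 fell by 1.71 ± 0.19 (adjusted p = 6.51e-08), 1.24 ± 0.16, 1.19 ± 0.15 and 0.84 ± 0.10. The chemokine CXCL8 rose by 2.01 ± 0.40 (adjusted p = 0.00212), ANGPTL4, a regulator of lipoprotein lipase, by 1.97 ± 0.28, IL24 by 1.84 ± 0.25, CYP1A1 by 1.81 ± 0.22, PTX3 by 1.65 ± 0.17, PTGS2, the inducible cyclooxygenase, by 1.64 ± 0.22 and CXCL1 by 1.32 ± 0.32. SEMA5B, REC8, ZNF467 and LOC100130417 fell by 1.82 ± 0.31, 1.26 ± 0.24, 1.25 ± 0.20 and 1.20 ± 0.29. CDC20 fell from 68.4 ± 4.41 to 49.4 CPM, by 0.47 ± 0.08 (adjusted p = 0.000392).

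Interferon-stimulated genes fell in 18 of 31 (26 adjusted over the list alone; median -0.54, adjusted p = 4.35e-38). Cholesterol synthesis genes fell in 13 of 26 (20 adjusted over the list alone; median -0.43, adjusted p = 2.99e-21), with FDFT1, HMGCS1 and INSIG1 at -0.59, -0.57 and -0.57. Genes of EGFR to ERK output rose in 14 of 26 (17 up and 1 down adjusted over the list alone; median 0.47, adjusted p = 1.91e-18), with DUSP5 at 1.02 ± 0.12, DUSP6 at 1.01 ± 0.13 and PHLDA1 at 0.72 ± 0.09. NF-kappaB cytokine genes rose in 11 of 23 and fell in 1 (16 and 1 adjusted over the list alone; adjusted p = 9.59e-15), with TNFAIP3 at 0.79 and ICAM1 at 0.77. Aryl hydrocarbon receptor targets rose in 5 of 11 (7 adjusted over the list alone; adjusted p = 6.07e-11), with TIPARP at 0.80 and CYP1B1 at 0.59. NRF2 genes rose in 7 of 26 (8 adjusted over the list alone; adjusted p = 5.29e-08), with SLC7A11 at 0.89, TXNRD1 at 0.53 and NQO1 at 0.48. Mesenchymal genes fell in 6 of 21 (7 adjusted over the list alone; adjusted p = 1.82e-05), with TGFBI at -0.49 and SPARC at -0.37. ATF4 and CHOP genes rose in 4 of 29 (11 adjusted over the list alone; adjusted p = 4.99e-05). With an estimated correlation these 8 lists passed at adjusted p = 1e-05, 0.00292, 0.00121, 0.0107, 0.00123, 0.0159, 0.0182 and 0.00524 in the order given.

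Mitosis genes fell in 5 of 30 (14 adjusted over the list alone; median -0.29, adjusted p = 9.81e-11, and adjusted p = 0.0755 with an estimated correlation), with KIF20A at -0.64 and PLK1 at -0.50. Replication genes rose in 1 of 32 (4 adjusted over the list alone; adjusted p = 6.89e-05, and adjusted p = 0.103 with an estimated correlation), and histone genes fell in 1 of 20 (3 adjusted over the list alone; adjusted p = 0.000129, and adjusted p = 0.0701 with an estimated correlation). Repair (0 of 22, adjusted p = 0.00334, and adjusted p = 0.332 with an estimated correlation), fibroblast (3 of 7 down, adjusted p = 0.00532, and adjusted p = 0.119 with an estimated correlation), hypoxia (2 of 31 down, adjusted p = 0.0115, and adjusted p = 0.152 with an estimated correlation) and endoplasmic reticulum chaperone genes (1 of 23 up, adjusted p = 0.0367, and adjusted p = 0.433 with an estimated correlation) passed only with the preset correlation. FOS was at -0.76 ± 0.26 (adjusted p = 0.104), EGFR at 0.30 ± 0.17 (adjusted p = 0.397), ERBB2 at -0.22 ± 0.11 (adjusted p = 0.333), ERBB3 at 0.04 ± 0.11 (adjusted p = 0.92), MET at 0.19 ± 0.13 (adjusted p = 0.528) and AXL at -0.17 ± 0.20 (adjusted p = 0.756). In all, 546 genes passed, 283 higher and 263 lower. Without gefitinib library 1 or 3 the count was 321 or 288, and without combination library 1 or 2 it was 322 or 297. LOC100130417 and CXCL1 each lost the call without at least 1 library, at adjusted p up to 0.088 and 0.071.

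At 5 mg/mL YFSJ with 50 µM gefitinib, CXCL8 rose by 1.83 ± 0.40, CXCL2 by 1.49 ± 0.31 and PTGS2 by 1.19 ± 0.22, and RASSF10, IGFBP5 and TM7SF2 fell by 1.20 ± 0.25, 1.07 ± 0.28 and 0.92 ± 0.16. Cholesterol genes fell in 11 of 26 (22 adjusted over the list alone) and genes of EGFR to ERK output rose in 10 of 26 (15 adjusted over the list alone). In all 148 genes passed, 84 higher and 64 lower, with 56.8% of calls higher, and 68.3% with library-size scaling. A fit of only the 6 libraries called 0 genes in edgeR, with 1384 at an unadjusted p under 0.05; DESeq2 with all libraries called 253, and 367 passed with a GC correction. CDC20 was at 75.2 ± 8.18 CPM against 68.3 ± 3.72 CPM alone (0.14, adjusted p = 0.553), and of the 30 mitosis genes 0 were called (1 up adjusted over the list alone; median 0.14). Without combination library 1, 2 or 3 the count was 10, 9 or 684, and without gefitinib library 1 or 2 it was 45 or 69. The calls of all 6 genes named here ended without combination library 1 or 2, at adjusted p of 0.0902 (TM7SF2) to 0.557 (IGFBP5). Those of CXCL8, CXCL2, RASSF10 and IGFBP5 also ended without at least 1 gefitinib library, at adjusted p up to 0.17 (IGFBP5).

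With 2.5 mg/mL YFSJ and 50 µM gefitinib, 14 genes passed. CYP1A1, SECTM1 and CEMIP rose by 1.26 ± 0.22, 1.23 ± 0.19 and 0.99 ± 0.19, and FOS, FOSB and DUSP1 fell by 2.20 ± 0.27, 2.19 ± 0.29 and 0.92 ± 0.13. The remaining fall was CDC20 (-0.46, adjusted p = 0.00576), named after the values were seen. Without gefitinib library 1, 2 or 3 the count was 5, 8 or 6, and without combination library 1, 2 or 3 it was 7, 6 or 9. CYP1A1 and CEMIP lost the call without gefitinib library 1 (adjusted p = 0.0686 and 0.219) or 3, and CEMIP also without combination library 2 or 3 (adjusted p = 0.116 and 0.0566). A fit of only the 6 libraries called 27. With 75 µM gefitinib 289 genes passed, 157 higher and 132 lower. A fit of only the 6 libraries called 0 in edgeR, with 2094 at an unadjusted p under 0.05, and DESeq2 with all libraries called 567. CYP1A1, IL24 and the thrombin receptor gene F2RL3 rose by 1.31 ± 0.23, 1.22 ± 0.26 and 1.06 ± 0.26, FOSB, IFI44L and LOC100130417 fell by 1.55 ± 0.27, 1.36 ± 0.18 and 1.30 ± 0.30, and 14 of 31 interferon-stimulated genes fell (20 adjusted over the list alone). Without combination library 2, which stood apart, 32 genes passed, and without library 1 or 3 of that group 653 or 1079. Without gefitinib library 1, 2 or 3 the count was 73, 80 or 29. IL24 and LOC100130417 lost the call without combination library 2 or gefitinib library 2 or 3 (adjusted p up to 0.0938 and 0.244). F2RL3 lost it without combination library 2 or any 1 gefitinib library (adjusted p up to 0.104).

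For YFSJ and gefitinib the interaction passed in 268 genes, 102 above the sum of the separate effects and 166 below. DESeq2 called 506, a fit with no filter 168 and an F test of the 4 terms together 87. Of the 268, 38.1% were above, and 27.6% with library-size scaling. DUSP1 and EDN1 lay above by 1.36 ± 0.14 (adjusted p = 1.33e-08) and 1.34 ± 0.17, and CYP1A1, ERVV-2 and CPAMD8 below, at -1.76 ± 0.28, -1.40 ± 0.31 and -1.27 ± 0.30. FOSB was at 1.30 ± 0.31 (adjusted p = 0.0197), and at 1.21 with adjusted p = 0.0598 with the batch term, which left 168 genes. Cholesterol genes were below in 12 of 26, aryl hydrocarbon receptor targets in 6 of 11 with 1 above, and interferon-stimulated genes in 7 of 31 (21, 7 and 15 adjusted over the list alone), and genes of EGFR to ERK output above in 5 of 26 (8 adjusted over the list alone). Without untreated library 1 or 2 the count was 98 or 81, without 50 µM gefitinib library 2 or 3 it was 137 or 512, and without 75 µM gefitinib library 3, 2.5 mg/mL library 3 or 5 mg/mL library 1 it was 178, 170 or 157. ERVV-2, CPAMD8 and FOSB lost the call without at least 1 untreated library, at adjusted p up to 0.102, 0.0964 and 0.0851, and CPAMD8 also without library 3 of 2.5 mg/mL YFSJ (adjusted p = 0.0643).

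Between the pairs at 75 µM gefitinib, HSPA6 (8.44 ± 0.18, adjusted p = 8.1e-35) and CDC20 (2.30 ± 0.09, adjusted p = 5.04e-25) were higher with 2 mg/mL CKI than with 5 mg/mL YFSJ, as were all 30 mitosis genes, 18 of 26 genes of EGFR to ERK output and 15 of 19 heat shock genes. CTSO, HTR3A and LOC100286925 were lower, at -2.80 ± 0.16, -2.79 ± 0.22 and -2.78 ± 0.29, as were 24 of 26 cholesterol genes. In all 8895 genes passed, 4416 higher and 4479 lower, and 6624 with the batch term, 3231 higher and 3393 lower. APOB, HP and FGA headed the rises through the liver-transcript libraries.

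Each combination was also set against the preparation alone, in comparisons added after the data were seen. Gefitinib at 50 and 75 µM changed 6163 and 7538 genes beside 1 mg/mL CKI (6688 for the latter with the batch term), 1746 and 4760 beside 2 mg/mL CKI (1181 and 2769 with the batch term), 8511 and 8135 beside 2.5 mg/mL YFSJ (5587 and 5361 with the batch term), and 8354 and 8108 beside 5 mg/mL YFSJ. The 1746 fell to 1065 without CKI library 3 and 1112 without combination library 1, and the 4760 to 3168 without combination library 3. Library-size scaling shifted the median of all genes by 0.149 and 0.11 beside 1 mg/mL CKI, and by 0.143 and 0.111 beside 5 mg/mL YFSJ. It shifted the median by 0.101 when 1 mg/mL CKI was added to 75 µM gefitinib and by 0.103 when 2 mg/mL was added to 50 µM.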

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

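Tests in this part were chosen after the result was seen, except the splits of the libraries and the correlations with GC share and gene length. A test of the difference picked out both interactions: the change with both agents was not the sum of the separate ones. This held in 6237 genes for CKI and 268 for YFSJ (edgeR). The permutation of residuals used limma on log2 CPM, with its own counts. Of 100 draws only the real one gave as many: 7175 against at most 1496 for CKI and 474 against at most 1 for YFSJ. This argues against chance labels only. The draws break up the groups, so any deviation that a group shares could also pass.

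With CKI at 2 mg/mL the response to gefitinib had a slope of 0.113 at 50 µM and 0.105 at 75 µM, against 0.841 and 0.818 with 5 mg/mL YFSJ. The batch with liver transcripts is argued against at 1 mg/mL CKI with 50 µM, where all 3 libraries lie outside it and the highest slope was 0.512, and stays open at 2 mg/mL, where 1 library lies outside it (0.144). Genes that CKI alone had already moved would leave a slope near 1 in genes it moved by under 0.25 (log2) and gefitinib by at least 1, and over 362 such genes it was 0.154 (SD 0.076, n = 3). A wrong gefitinib treatment at 1 mg/mL CKI would leave slopes near 0 or near 1, and the lowest of its 6 libraries had 0.47. Libraries of 2 mg/mL CKI that lack gefitinib would match CKI alone. Against CKI alone, 1746 genes were called at 50 µM (1181 with the batch term) and 4760 at 75 µM. Median levels of cholesterol synthesis genes relative to untreated cells at 24 h averaged 0.453 (SD 0.022, n = 3) with CKI alone. With 50 and 75 µM gefitinib they averaged -0.115 (SD 0.06) and -0.099 (SD 0.064), with -0.178 in the 50 µM library outside the batch. These values argue against missing gefitinib for this list, while replication genes stayed near CKI alone (-1.17, -1.22 and -1.11). Over the genes called for gefitinib alone, the changes correlated with those it made alone at 0.33 (SD 0.073, n = 3) and 0.246 (SD 0.156). This was not above the 0.3 set as exclusion by more than the SD (a margin added after these values were seen), so that test stays open. An effect of CKI on the cells or on the gefitinib that reaches them was not measured.

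ALB and other liver and intestine transcripts were present in 10 libraries and near 0 in the other 38. Induction by the treatment would raise them alike in the replicates of a group, but the highest ALB count was 826 times the lowest within 1 group. A batch change that moves abundant genes by over 1 (log2) is argued against: 0 of 7795 genes with at least 20 CPM outside the marker lists moved so. The shift had to be alike in both groups that hold libraries of both kinds, and smaller shifts were not tested. One among scarcer genes stays open: 82 genes outside the lists moved in this way, 4 of them downwards, among the rest the noncoding RMRP (4.86 and 3.16) and RPPH1 (4.33 and 3.03), and RPPH1 also had 320 counts in library 1 of 5 mg/mL YFSJ, which had 1 ALB count. RNA of liver or intestine mixed into these libraries may be the source of the liver transcripts, since 23 of 30 liver markers were higher in all 10 than in any other library. The lowest correlation across the list between any pair of the 10 was 0.951. That value does not single out mixed RNA: ALB, which chose the 10, is a list member, and members such as SERPINA1 (at least 793 counts) were expressed in the other libraries too. The labels name no such tissue, and where it entered was not tested.

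At 0 h, libraries 1 and 2 differed from library 3, and the count of genes between 24 h and 0 h was 147 with library 3 alone. GC share took up 2.95% of the variance of that difference across genes and gene length 6.53%, so neither is the whole of it. A part remains open for both, with Spearman correlations of -0.091 and 0.266, since the value for GC share lies under the 0.1 set beforehand as its exclusion by less than its spread (its size plus 2 SE is 0.107); that spread was added to the bound after the value was seen. Blood cells in library 1, where CCL3 had 311 counts and IL1B 201, also stay open, with 6 of 20 blood markers higher there than in the other 5 untreated libraries, PTPRC at 8 against at most 1 count and LYZ at 43 against at most 2. No biological explanation was tested, since the design gives 1 label to all 3.

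For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In fits of the 6 libraries the real split alone gave as many genes in 26 of 28 comparisons (1 of 10 splits each), with 0 genes as the highest other in all of these but 2.5 mg/mL YFSJ with 50 µM gefitinib, at 27 genes against 1. At 2.5 mg/mL YFSJ with 75 µM the real split and all others gave 0 (10 of 10). At 5 mg/mL with 50 µM it gave 0 and all 10 splits were as large. Gefitinib libraries 1 and 2 with combination library 3 gave 385, and leaving out the last gave 684. Library 3 lay nearer gefitinib alone than its replicates in PC2 (-25.8 against -16.6 and -18.6) and CYP1A1 (2.72 against 6.70 and 6.74 CPM). LSS and DUSP6 did likewise, CDC20, CHAC1 and HSPA6 did not. Each library's deviation from its replicates correlated with GC share (Spearman) at 0.299, 0.559 and -0.663 for gefitinib libraries 1, 2 and 3. The combination libraries gave 0.206, -0.468 and 0.28, and untreated ones -0.505 to 0.517 at 24 h and -0.12 to 0.091 at 0 h. Whether GC share or a library without YFSJ made the split was not tested.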

How the results depend on the processing

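Library-size scaling, the batch term, the lone libraries, the GC correction and the comparisons of combinations with the preparation alone were chosen after the data were seen; all else was planned. Where a count changed, the cause was not tested, except that a stricter threshold calls fewer genes by construction. All 30 counts stayed within 1.5 times of their value with relative log expression factors and with a block for the replicate number (5 mg/mL YFSJ: 933), 29 with no filter or library-size scaling, 26 with DESeq2, 25 with a GC correction and 24 with the batch term. The block rests on numbers that did not pair libraries: across groups, same-numbered libraries correlated at -0.0086 on average and differently numbered ones at 0.00423. With the block ERBB3 in 2 mg/mL CKI with 75 µM gefitinib passed (adjusted p = 0.0472), and the NRF2 list at 24 h did not (0.0513, and 0.0548 with relative log expression factors). Of 380 values of named genes 379 kept direction and side of the threshold with relative log expression factors, 378 with the block and with no filter, 373 with DESeq2, with library-size scaling and with the GC correction, and 357 with the batch term, as did 2522 of 2637 values with 1 library left out. Of 150 pairs of list and comparison 74 passed camera, and 33 with an estimated correlation.

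Library-size scaling gave 185 genes for 2.5 mg/mL YFSJ with 75 µM gefitinib against gefitinib alone. With no filter the YFSJ interaction had 168. DESeq2 gave 39, 567 and 253 genes for 2.5 mg/mL YFSJ with 50 and 75 µM and 5 mg/mL with 50 µM gefitinib, and 506 for the YFSJ interaction. In fits of the 6 libraries alone 24 h against 0 h had 93, 2.5 mg/mL YFSJ with 50 µM 27, 5 mg/mL with 75 µM 1085, 75 against 50 µM gefitinib 2, and 5 against 2.5 mg/mL YFSJ 95. In the same edgeR fits 2.5 mg/mL YFSJ with 75 µM had 0 genes (2094 at an unadjusted p under 0.05; DESeq2 with all libraries 567) and 5 mg/mL with 50 µM had 0 (1384; DESeq2 253). The F test of 4 terms left 87 for the YFSJ interaction. At adjusted p under 0.01 the counts were 2089 for 24 h, 2884 for 1 mg/mL CKI, 165 and 364 for 2.5 and 5 mg/mL YFSJ, 3223 for 1 mg/mL CKI with 50 µM gefitinib, 8 and 35 for 2.5 mg/mL YFSJ with 50 and 75 µM, 47 and 269 for 5 mg/mL, 3287 for 2 against 1 mg/mL CKI, 25 for 5 against 2.5 mg/mL YFSJ and 75 for the YFSJ interaction. The batch term left 48 for 2.5 mg/mL YFSJ, 168 for the YFSJ interaction and, in edgeR, 0 for 5 against 2.5 mg/mL YFSJ (397 at an unadjusted p under 0.05; DESeq2 without the term 43). The library outside the batch gave 5634 for 2 mg/mL CKI with 50 µM gefitinib, and library 3 of the 0 h group 147 for 24 h; a lone library is assumed to vary like the other groups. The GC correction gave 745 for 2.5 mg/mL YFSJ, 36 for it with 50 µM gefitinib, 367 and 896 for 5 mg/mL with 50 and 75 µM, and 8 for 75 against 50 µM.

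With 1 library left out the counts ran from 1070 to 6029 for 24 h, 162 to 354 and 407 to 902 for 2.5 and 5 mg/mL YFSJ, 81 to 512 for the YFSJ interaction, 5 to 9 and 29 to 1079 for 2.5 mg/mL YFSJ with 50 and 75 µM gefitinib, 9 to 684 and 288 to 465 for 5 mg/mL, 2 to 7 for 75 against 50 µM gefitinib and 18 to 45 for 5 against 2.5 mg/mL YFSJ. Some log2 values changed sign, none of them past the threshold there. EGFR with 75 µM gefitinib was at 0.064 with library-size scaling, 0 with the GC correction and -0.071 to 0.023 with 1 library left out. MET with 2 mg/mL CKI was at 0.135 with library-size scaling and -0.146 to 0.028 with 1 library left out. CDC20 between CKI doses was at 0.006 with library-size scaling, and FGB between YFSJ doses at 2.399 with the batch term. With 1 library left out ERBB3 and NQO1 with 2 mg/mL CKI ran from -0.096 to 0.204 and from -0.014 to 0.068. CDC20 with 5 mg/mL YFSJ ran from -0.076 to 0.054, and ERBB3 with 5 mg/mL YFSJ and 75 µM gefitinib from -0.087 to 0.142. Depth limits genes near 0.183 CPM, the floor of the smallest library.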

Other observations

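The stress cytokine gene GDF15 was at 14.5 ± 2.83 CPM (SD, n = 3) in untreated cells at 24 h, 136 ± 7.38 with 75 µM gefitinib, 131 ± 16.1 with 1 mg/mL CKI, 419 ± 38.2 with 2 mg/mL CKI and 353 ± 14 with the latter and 75 µM gefitinib. FOS, an immediate early gene, was at 12.7 ± 2.48 CPM at 0 h and 74.1 ± 8.69 CPM at 24 h, and at 19.2 ± 1.05 and 14.5 ± 0.337 CPM with 2.5 and 5 mg/mL YFSJ. With 50 µM gefitinib FOS was at 103 ± 5.21 CPM alone, 22.4 ± 2.3 with 2.5 mg/mL YFSJ and 149 ± 47.9 with 5 mg/mL YFSJ. With 75 µM gefitinib it was at 92.2 ± 6.15 CPM alone, 37.9 ± 23.3 with 2.5 mg/mL YFSJ and 54.4 ± 4.58 with 5 mg/mL YFSJ. The cytokine gene IL24 was highest with 1 mg/mL CKI and 50 µM gefitinib, at 72.5 ± 3.49 CPM, against 28.3 ± 3.02 with that CKI dose alone, 3.42 ± 0.232 with that gefitinib dose alone and 1.62 ± 0.393 in untreated cells.

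Several lists had members moving both ways with 75 µM gefitinib. Hypoxia and glycolysis genes rose in 11 of 31 and fell in 12 (11 and 13 adjusted over the list alone; adjusted p = 0.521). Endoplasmic reticulum chaperones rose in 8 of 23 and fell in 8 (9 and 9 adjusted over the list alone; adjusted p = 0.901), and replication-dependent histones rose in 8 of 20 and fell in 4 (adjusted p = 0.462). Mesenchymal genes rose in 3 of 21 and fell in 7 (adjusted p = 0.166). Ribosomal protein genes rose in 1 of 34 and fell in 14 (1 and 12 adjusted over the list alone; adjusted p = 0.114). NRF2 genes rose in 9 of 26 and fell in 6 (11 and 6 adjusted over the list alone; adjusted p = 0.223). Genes of drug efflux and metabolism fell in 5 of 16 (4 adjusted over the list alone; adjusted p = 0.266), and with 2 mg/mL CKI added rose in 8 and fell in 4 (adjusted p = 0.349). Of the cell type markers, 5 of 15 luminal breast genes rose and 2 fell (adjusted p = 0.559), as did 3 and 2 of 9 alveolar and airway genes (adjusted p = 0.699), 1 and 1 of 8 blood cell genes (adjusted p = 0.739) and 3 and 1 of 7 fibroblast genes (adjusted p = 0.37). With 2 mg/mL CKI alone 4 of 8 blood cell genes rose and 1 fell (median 0.89, adjusted p = 0.307), as did 2 and 4 of 9 alveolar and airway genes (median -0.09, adjusted p = 0.608) and 4 and 4 of 15 luminal breast genes (adjusted p = 0.608). With it and 75 µM gefitinib, against gefitinib alone, 2 of 8 blood cell genes rose and 1 fell (2 and 0 adjusted over the list alone; median 0.74, adjusted p = 0.378), as did 2 and 2 of 9 alveolar and airway genes (median -0.36, adjusted p = 0.705) and 6 and 4 of 15 luminal breast genes (adjusted p = 0.57). Against untreated cells the medians with both agents were 0.87 for blood cell genes and 0.63 for alveolar and airway genes.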
